A study of Mus musculus with 6 samples.

How the data were processed

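RNA was measured in mouse retinas taken at postnatal day 0 and kept for 7 days as explants floating on membrane filters, from Sall3 knockout and wild-type animals. The labels describe 6 samples in 2 groups of 3, each made from RNA of 3 pooled retinas and hybridised to its own Affymetrix mouse exon array. Groups and sample numbers were taken from the sample titles.

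The deposited table gives 1 value per transcript cluster, a group of probes placed along the exons of a putative transcript, for 100843 clusters on 6 arrays. The deposited values are on a log2 scale, as inferred from their range of 1.48 to 13.86, which spans a scanner's range in log2 units. Affymetrix Expression Console, PLIER (a method that summarises the probes of an exon array) and the mouse genome build mm8 are named per the submitters' processing notes, without versions, roles or order. The normalization between arrays, any constant added before the logarithm and the background correction are not given in the sources used here. No detection value came with the clusters, so how far a dim cluster lies above background is unknown, and a background signal would make a fold change smaller than the change in RNA. For arrays, it can be said of depth only that their number limits the precision: 3 per group leave 4 residual degrees of freedom. The column medians lay between 4.97 and 5.07.

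The following choices were made before the data were examined: the design, the tests, the gene lists, the rule for naming genes and most alternatives. Because the column medians differed by 0.103, just above the tolerance of 0.1 set in advance, the values were quantile normalized between arrays. Clusters were kept where their mean over the 6 arrays reached the 25th percentile, a log2 value of 3.70, which left 75632. Control clusters could not be told from others by the tables used here, so none was removed by name.

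Names came from a table that pairs clusters with gene symbols of the platform annotation. Of all clusters, 22608 had 1 symbol, 1462 had several and 76773 were unnamed here; no gene was named from a cluster with several symbols. Of the clusters with 1 symbol, 22101 were matched through gene identifiers to a RefSeq gene table of assembly GRCm38 and took its symbol, and 507 kept the annotation's name. That assembly differs from mm8, so no coordinates are printed and the table served only for names. Each gene was represented by its kept cluster with the highest mean over all arrays, which gave 17468 genes. Where other clusters of a named gene went the opposite way, this is stated.

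The knockout was compared with wild-type in a 2-group model with lmFit and eBayes in limma 3.58.1 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all kept clusters and a threshold of 0.05. All adjusted p-values come from limma. Changes are knockout minus wild-type on the log2 scale with the moderated standard error (SE). The 30 gene lists, with 394 genes of which no list shared any with another, covered cell types of the retina, tissues that dissection could carry over, stress and growth programmes, the Spalt family and genes near Sall3 on its chromosome. Of these genes 346 were measured, 28 had no named cluster used here, 11 lay only on a cluster with several symbols and 9 fell below the level filter. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 30 lists. Beside it stand camera with a correlation estimated per list, and fry, which tests whether a list's genes move on balance to the same side and does not compare them with other genes. Members were also adjusted over their list alone. For Sall3 an exact permutation test was added, whose smallest possible p with 3 samples per group is 0.1.

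The genes named in the text followed a rule. It took the 4 Spalt genes, the genes past the threshold with the 12 largest rises and falls or, where none passed, the 10 with the smallest p in that direction, given as not passing. It also took all members of the cone and horizontal cell lists and up to 4 members with the smallest p of every other list.

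Alternatives were the values as deposited, median centring, no filter and a filter at the 50th percentile, a variance trend with intensity, robust variances, array weights, the sample number as a replicate block, each array left out in turn, 1 row per gene, a looser threshold of 0.1, a fold minimum of 1.5, and the mean of a gene's clusters. Chosen after seeing the data were 1 row per gene together with an intensity trend, the cone list without Opn1sw and Pde6c, each array left out with the correlation estimated per list, and the counts of list members under each alternative. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

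The comparison was tested on simulated data with 75632 clusters and 17468 genes, in 5 runs with 200 changed genes each and independent genes of normal spread. With variances drawn from the distribution that limma fitted, 53.4% of genes shifted by a log2 value of 1 and 94.8% of those shifted by 2 were called over all clusters, and 87.0% and 97.8% with 1 row per gene. This way of drawing variances was added after the results were known. The earlier version, which gave each cluster its moderated spread, called 39.0% and 96.6% over all clusters. Calls outside the 200 genes of a run numbered 28 over the 5 runs, and 27 in the earlier version. The adjusted threshold depends on how many genes change, so these rates do not give the power where fewer than 200 change. Nor do they give it for genes as variable as Opn1sw, with a wild-type SD of 0.68. A shift of the whole cone list by -0.2 was called by camera with the preset correlation in 5 of 5 runs. With an estimated correlation it was called in 1 of 5 runs and, in the earlier version, in 0 of 5, so that test had little power for a shift of this size. Because the simulated genes were independent, the runs do not show how often the preset test calls unshifted lists of correlated genes. In the data the estimated correlation of the cone list was 0.42.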

Results

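Gene expression was compared between retinal explants from Sall3 knockout and wild-type mice, with 3 arrays per genotype. Sall3 encodes a zinc finger transcription factor of the Spalt family. Each sample pooled 3 retinas isolated on the day of birth and cultured for 7 days. The title of the series names cone photoreceptors and horizontal cells, the retinal interneurons that contact photoreceptor terminals, so the lists of genes typical of these cell types were the main comparisons. The labels describe the samples as made in triplicate but do not say whether they came from separate litters or culture runs, so p-values measure the spread between these samples. Correlations between arrays of the same genotype ranged from 0.954 to 0.977, and those between genotypes from 0.940 to 0.970. These ranges overlapped, so the arrays did not separate by genotype on this measure. Knockout 1 stood apart along the axis of largest variance, which held 31.9% of it, at -98.5 against 11.7 and 11.9 for knockout 2 and knockout 3, and wild-type 3 lay on the other side, at 62.5 against 9.54 and 2.87 for wild-type 1 and wild-type 2.

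The targeted gene was examined for a difference between the genotypes. Sall3 (cluster tc6866962) had a log2 signal of 6.14 ± 0.10 (SD, n = 3) in knockout and 6.30 ± 0.08 (SD, n = 3) in wild-type explants. The change of -0.16 (SE 0.10, 95% interval -0.42 to 0.09) was within the spread between samples (limma adjusted p = 0.877; exact permutation p = 0.2, two-sided). Knockout 1 at 6.24 lay above wild-type 1 at 6.21. Where the probes of this cluster lie relative to the targeted part of the gene is not known, so the value does not check the genotype labels. Among the related genes, Sall1 differed by -0.22 (SE 0.18) and Sall4 by -0.03 (SE 0.09), both with overlapping groups, and a dimmer cluster of Sall4 had a value of 0.00. Without wild-type 1 Sall1 stood at -0.06, and Sall4 changed sign without knockout 3. Sall2 lay only on a cluster with several symbols and was not analysed here. For the 3 Spalt genes measured, the list median was -0.16 (camera adjusted p = 0.308), and -0.06 without wild-type 1.

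Across all genes, the lowest p-values in the direction of lower signal in knockout belonged to genes of several kinds, none of which passed the adjusted threshold. Among them were Fos at -2.64 (SE 0.35) and Egr1 at -2.07 (SE 0.23), transcription factors induced within minutes of stimulation. Opn1sw, the short-wavelength cone opsin, stood at -2.35 (SE 0.37) and Pde6c, the catalytic subunit of the cone phosphodiesterase, at -1.08 (SE 0.14). Bsnd, which encodes the chloride channel subunit barttin, stood at -1.85 (SE 0.18), the Tie2 ligand Angpt2 at -1.42 (SE 0.23) with both of its clusters lower, and the proprotein convertase Pcsk6 at -1.24 (SE 0.15). The remaining ones were Lhx1, a LIM homeodomain factor of horizontal cells, at -0.77 (SE 0.11), the ribonucleotide reductase subunit Rrm2b at -0.67 (SE 0.09), and Vmn1r198, a dim vomeronasal receptor gene of a large family, at -1.08 (SE 0.11). In each of these 10 genes all knockout arrays lay below all wild-type arrays.

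In the opposite direction the 10 lowest p-values belonged largely to genes with little known function. The splicing kinase gene Clk2 stood at 0.84 (SE 0.11) and Penk, the precursor of enkephalin peptides, at 1.01 (SE 0.20). The transcripts A230107N01Rik, C030016D13Rik, 4732440D04Rik and 1700055D18Rik had values of 1.45, 1.28, 0.84 and 0.43, the predicted gene Gm7285 0.77, and the dim olfactory receptor gene Olfr978 1.19. Thrap3, an mRNA processing factor, stood at 0.81, with its dimmer clusters at -0.02 and -0.03. The imprinted noncoding RNA Kcnq1ot1 stood at 0.77 on its brightest cluster, while 2 of its 6 clusters had the opposite sign; without knockout 2 another cluster became the brightest, at -0.39, and the sign also turned without knockout 1 or without knockout 3. None of the 75632 clusters passed in limma in either direction (smallest adjusted p = 0.539). At an unadjusted p under 0.05 there were 2511 higher and 2458 lower, where 3781.6 in all would be given by chance. In the same fit the 17468 gene rows gave 95 higher and 184 lower, against 873.4 by chance, so the excess lay in the other clusters. With 1 row per gene 0 passed as well (smallest adjusted p = 0.145), with 184 higher and 594 lower at the unadjusted threshold, in all fewer than the 873.4 given by chance. The balance of directions depends on the scaling. Of the gene rows at this threshold in the fit over all clusters, 65.9% were lower after quantile normalization, 52.4% as deposited and 57.7% after median centring.

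Of the 15 genes of cone photoreceptors, all measured, 11 had lower and 4 higher values in knockout explants, and the sizes ranged widely. Of these, 3 fell and 0 rose when adjusted over the list alone, against 0 over all clusters tested. Opn1sw fell 5.08-fold, from a log2 signal of 9.94 ± 0.68 in wild-type to 7.60 ± 0.33 in knockout (SD, n = 3; limma adjusted p over the list = 0.00574). Pde6c fell 2.11-fold, from 9.01 ± 0.20 to 7.93 ± 0.15 (SD, n = 3; limma adjusted p over the list = 0.00497). Arr3, the cone arrestin, fell by 0.51 (SE 0.13, limma adjusted p over the list = 0.0398). This call was lost in the absence of any array except knockout 1, and also under median centring and with the replicate block.

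The other 12 cone genes had a median of -0.11 and ranged from -0.25 to 0.12, and none passed in the main fit. The middle-wavelength opsin Opn1mw had a value of -0.24 (SE 0.16), and of -0.09 without wild-type 1. The cone transducin subunits Gnat2 and Gngt2 stood at -0.18 (-0.11 without wild-type 1) and -0.20 (-0.13 without wild-type 2). The channel subunit Cnga3, at -0.25 (SE 0.09), passed over the list alone with the values as deposited and with array weights. The exchanger Slc24a2 stood at -0.25, Ccdc136 at -0.22 and the inhibitory phosphodiesterase subunit Pde6h at -0.04. The main fit moderates variances over all clusters, whose median residual SD was 0.247 against 0.0992 for genes, which widens the SEs of genes. With 1 row per gene the SEs of Cnga3 and Ccdc136 were 0.056 and 0.063 (limma unadjusted p = 0.00408 and 0.0130). Adjustment over the list alone was not run in that fit. Values near 0 that changed sign in at least 1 alternative setting were those of Gnb3 (-0.01), the thyroid hormone receptor Thrb (0.01), the retinoid receptor Rxrg (0.04), Otop3 (0.04) and the channel subunit Cngb3 (0.12). The list median was -0.20 and its mean -0.34, and camera placed the list below other genes (limma adjusted p = 2.67e-05; adjusted p = 0.974 with an estimated correlation; fry adjusted p = 0.656). The list medians of the single arrays, relative to the wild-type mean, were -0.11, -0.18 and -0.25 in knockout 1, 2 and 3 and 0.08, 0.03 and -0.12 in wild-type 1, 2 and 3. Without wild-type 1, which had the highest Opn1sw signal, the list median was -0.11.

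**Figure D1:**
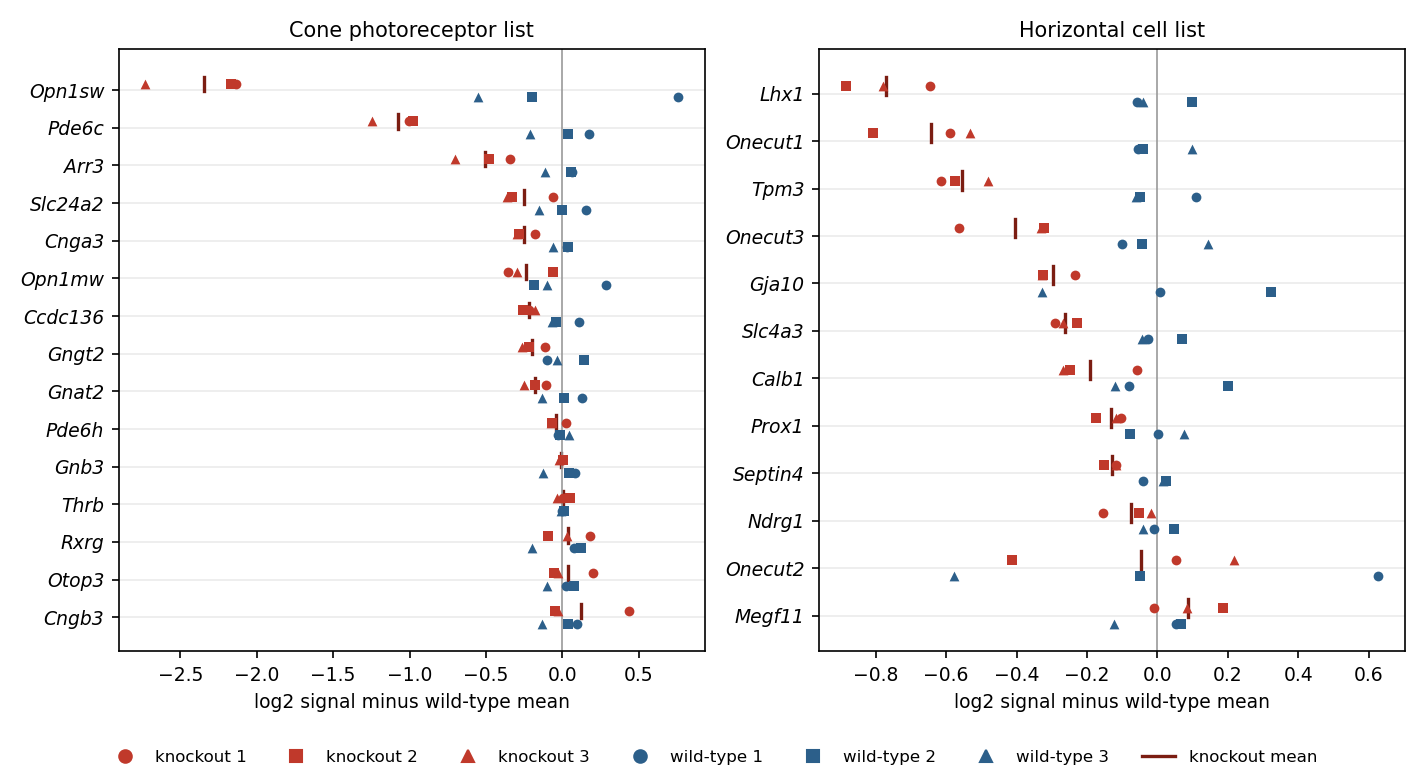
Log2 signal of each array minus the wild-type mean for the 15 cone genes (left) and the 12 horizontal cell genes (right); red symbols are knockout 1 to 3, blue symbols wild-type 1 to 3, and dark bars the knockout mean. Opn1sw at -2.35 and Pde6c at -1.08 stand far from the other cone genes, while Lhx1, Onecut1 and Tpm3 lead the horizontal cell genes at -0.77, -0.64 and -0.56.

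Of the 12 horizontal cell genes measured, 11 had lower values in knockout, and the 2 largest differences were those of transcription factors of that cell type. Of these, 3 fell and 0 rose when adjusted over the list alone, against 0 over all clusters tested. Lhx1 fell from 7.75 ± 0.09 to 6.98 ± 0.12 (SD, n = 3; limma adjusted p over the list = 0.00538). Onecut1, a factor that directs horizontal cell formation, fell by 0.64 (SE 0.12; limma adjusted p over the list = 0.00648), and its other cluster stood at -1.06. Tpm3, a tropomyosin gene, fell by 0.56 (SE 0.10; limma adjusted p over the list = 0.00648). All 3 calls were made again whichever array was left out.

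The related factor Onecut3 missed the threshold narrowly, at -0.41 (SE 0.12; limma adjusted p over the list = 0.0502). The remaining values were -0.26 for the anion exchanger Slc4a3, -0.30 for the connexin gene Gja10, -0.19 for the calcium-binding protein calbindin (Calb1), and -0.13 for both Prox1 and Septin4. Without wild-type 2 Gja10 stood at -0.13 and Calb1 at -0.09. Onecut3 and Slc4a3 passed over the list alone with the filter at the 50th percentile, with an intensity trend and with array weights. With 1 row per gene, where the list alone was not adjusted, their limma unadjusted p was 0.00539 and 0.00220. Ndrg1 stood at -0.07. Onecut2 stood at -0.05 (SE 0.34) with all 8 of its clusters below 0, and Megf11 at 0.09 with its dimmer cluster at -0.22; both of these genes changed sign in at least 1 alternative setting. The list median was -0.23 and its mean -0.29 (camera adjusted p = 7.19e-09; adjusted p = 0.123 with an estimated correlation; fry adjusted p = 0.0152). List medians of -0.19, -0.28 and -0.27 in knockout 1, 2 and 3 lay below the -0.02, 0.04 and -0.04 of wild-type 1, 2 and 3. The Adra2a gene of this list had no named cluster used here. Factors that act earlier in the formation of horizontal and amacrine cells had a median of 0.00 over 5 genes (camera adjusted p = 0.869), which changed sign with an array left out. Foxn4 stood at -0.05, Neurod4 at 0.28, Tfap2a at -0.03 and Tfap2b at 0.01. Neurod4 stood at 0.04 without wild-type 3, and Tfap2a and Tfap2b changed sign with an array left out. Without wild-type 2 the horizontal cell list median was -0.15.

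The immediate early genes, which cells switch on within minutes of depolarisation, growth factors or mechanical stress, were lower in knockout explants in all 11 members. Adjusted over the list alone, 7 fell, against 0 over all clusters tested. Fos fell 6.23-fold, from a log2 signal of 9.09 ± 0.66 to 6.45 ± 0.25, and Egr1 fell 4.20-fold, from 9.81 ± 0.42 to 7.74 ± 0.12 (SD, n = 3; limma adjusted p over the list = 0.00158 and 0.00117). The phosphatase gene Dusp1 fell by 0.85, the nuclear receptor Nr4a1 by 0.99, Ier2 by 0.96, Junb by 0.67 and the antiproliferative gene Btg2 by 0.39. Not passing were Fosb, with 6.39 ± 0.78 in wild-type and 5.39 ± 0.07 in knockout (SD, n = 3), Egr2 at -0.46, Atf3 at -0.22 and Jun at -0.14. Fosb did pass over the list alone under median centring, with array weights, with the replicate block, without wild-type 1 and without wild-type 3. Atf3 passed with array weights and without knockout 1.

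The median of this list was -0.85 (camera adjusted p = 3.20e-14; adjusted p = 0.306 with an estimated correlation; fry adjusted p = 0.0679). Wild-type arrays differed among themselves, with list medians of -0.30, -0.11 and 0.47 in wild-type 1, 2 and 3, against -0.63 and -0.91 in knockout 1 and 3 and a still lower value in knockout 2. Without wild-type 3 the median was -0.55, and the number of members passing over the list alone was 3 without knockout 2 and 4 without knockout 3. Calls for Nr4a1, Ier2 and Junb were lost without knockout 2 or without knockout 3, that for Nr4a1 also without knockout 1, and that for Btg2 without knockout 2.

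**Figure D2:**
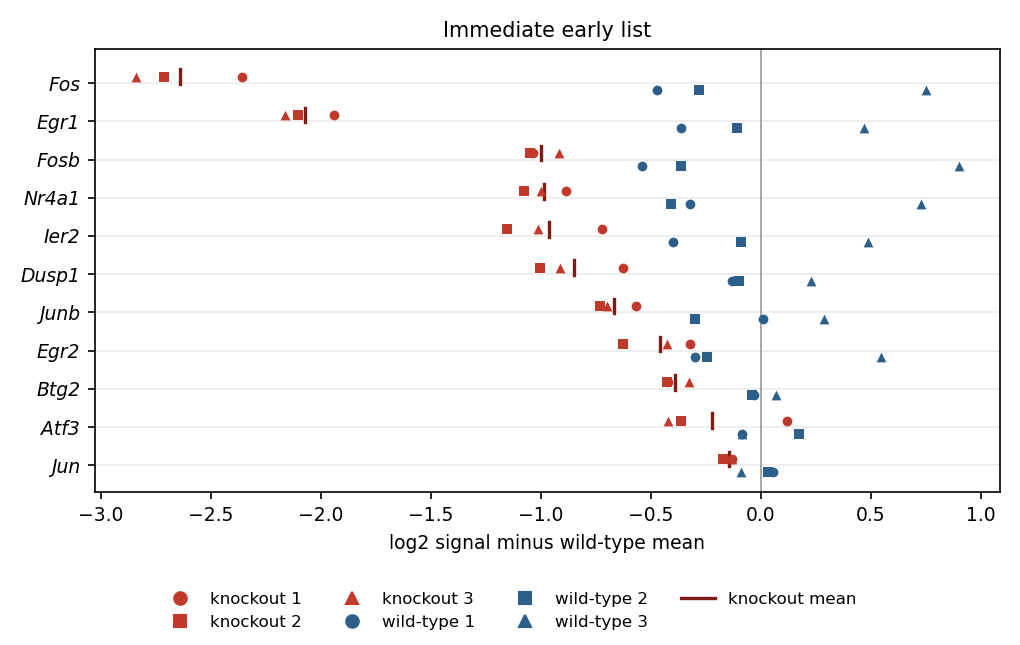
Log2 signal of each array minus the wild-type mean for the 11 immediate early genes; red symbols are knockout 1 to 3, blue symbols wild-type 1 to 3, and dark bars the knockout mean. All knockout arrays lie below all wild-type arrays in every gene except Atf3, and wild-type 3 has the highest signal in most genes.

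Other neurons and glia of the retina showed list medians close to 0, and camera called none of their lists. Rod photoreceptor genes had a median of 0.04 over 15 genes (camera adjusted p = 0.557). The orphan receptor Esrrb stood at -0.41, the transducin subunit Gngt1 at 0.58, the channel subunit Cnga1 at 0.49 and the rod determinant Nrl at -0.10. Gngt1 fell to 0.35 without knockout 1, and without wild-type 3 Cnga1 stood at 0.28 and Nrl at -0.06. Genes shared by rods and cones had a median of 0.03 over 22 (camera adjusted p = 0.474), with the guanylate cyclase activator Guca1a at -0.47. Bipolar cell genes had a median of 0.02 (-0.07 without knockout 1), with Grik1 at -0.35 and Tacr3 at 0.37 (0.18 without knockout 1). Amacrine cell genes had a median of 0.00, with the glutamate decarboxylase Gad2 at 0.34. Retinal ganglion cell genes had a median of -0.02, with the neurofilament genes Nefm at -0.41 (SE 0.12) and Nefl at -0.42 (SE 0.18). Müller glia genes had a median of 0.01 and astrocyte genes 0.03. No member of these lists passed when adjusted over its list alone. Retinal progenitor genes had a median of -0.01, where the mean of 0.01 and camera's direction had the opposite sign, and cell proliferation genes one of 0.01. Apart from the rod list and the list shared by rods and cones, all medians in this paragraph changed sign with an array left out. The medians of the rod list and the shared list fell to 0.01 and 0.00 without wild-type 3.

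Genes of the microglia and macrophage list were lower in 13 of 15 members with a median of -0.09 (camera adjusted p = 0.255). The fractalkine receptor Cx3cr1 stood at -0.37 (SE 0.19), and at -0.20 without knockout 3. In this list knockout 1 stood at 0.12, while knockout 2 and knockout 3 stood at -0.19 and -0.22. Without knockout 1 the median was -0.29 and camera called the list (adjusted p = 0.00122), and with array weights it was -0.24 (adjusted p = 0.00836). The call without knockout 1 was lost again with its correlation estimated (adjusted p = 0.648 with an estimated correlation), and with all arrays adjusted p = 0.974 with an estimated correlation. Knockout 1 also lay above the other arrays in the bipolar list at 0.22, the Müller glia list at 0.19, the astrocyte list at 0.29 and the interferon response list at 0.21.

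**Figure D3:**
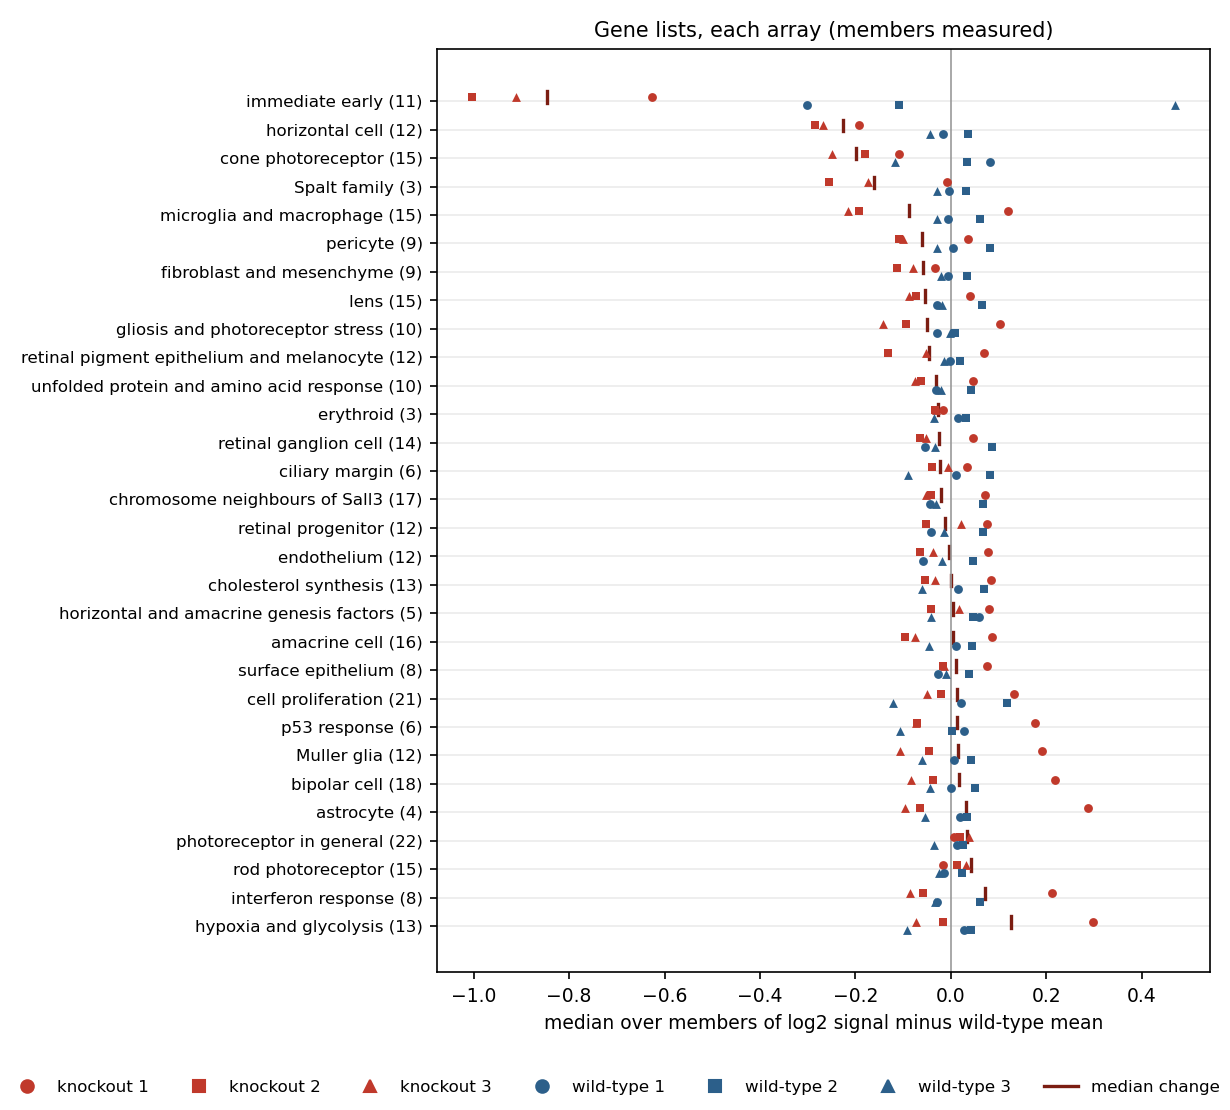
Median over the measured members of each of the 30 gene lists, as log2 signal of each array minus the wild-type mean; red symbols are knockout 1 to 3, blue symbols wild-type 1 to 3, dark bars the median change, and the number of members is in parentheses. The immediate early list at -0.85, the horizontal cell list at -0.23 and the cone list at -0.20 lie lowest, and knockout 1 lies to the right of the other arrays in many lists.

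Tissues that dissection could carry over gave no list that camera called at the preset correlation. Medians were -0.06 for fibroblasts and mesenchyme (adjusted p = 0.218), -0.06 for pericytes, -0.05 for lens, -0.05 for retinal pigment epithelium and melanocytes, -0.02 for the ciliary margin (where camera's direction was up), 0.01 for surface epithelium, 0.00 for endothelium and -0.03 for the 3 erythroid genes measured. Those of the ciliary margin, surface epithelium and endothelium changed sign with an array left out. The pericyte list and the retinal pigment epithelium and melanocyte list both stood at -0.01 without knockout 2, and the lens list at -0.02 without knockout 3. Fn1, the fibronectin gene, stood at -0.29 (SE 0.16), or -0.19 without wild-type 1, and the lens crystallin Cryga at -0.24 (SE 0.10). The fibroblast and mesenchyme list was called with the values as deposited, at -0.04 (adjusted p = 0.0475), and with the filter at the 50th percentile, at -0.11 (adjusted p = 0.0289). In the main setting this list had an adjusted p = 0.974 with an estimated correlation.

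Among stress and metabolic programmes, hypoxia and glycolysis genes were highest, with a median of 0.13 over 13 genes (camera adjusted p = 0.0959). The glycolytic genes Pgk1 and Ldha stood at 0.47 (SE 0.13) and 0.37 (SE 0.19), and 2 dimmer clusters of Ldha at -0.03 and -0.22. Without wild-type 3 Ldha stood at 0.23. In this list knockout 1 stood at 0.30, and knockout 2 and knockout 3 at -0.02 and -0.07, and without knockout 1 the median changed sign, to -0.02. Medians were 0.07 for the interferon response, 0.01 for the p53 response, -0.05 for gliosis and photoreceptor stress, -0.03 for the unfolded protein and amino acid response and 0.00 for cholesterol synthesis, none of which camera called and all of which changed sign with an array left out. The 17 genes near Sall3 on its chromosome had a median of -0.02 (camera adjusted p = 0.945), which changed sign with an array left out. Nfatc1 stood at -0.11, Zfp516 at -0.11 (-0.06 without knockout 1) and Ctdp1 at -0.06 (-0.02 without wild-type 2). Zfp236 stood at 0.14 (0.06 without wild-type 2), and its other cluster at -0.04.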

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

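The counts of list members under each setting, an estimated correlation with an array left out, the cone list without Opn1sw and Pde6c, and 1 row per gene with an intensity trend were chosen after seeing the data. No cluster passed in limma under any alternative run for the counts, where the smallest adjusted p ranged from 0.0808 without wild-type 3 to 0.803 without knockout 3. Sall3 ranged from -0.21 to -0.11 with an array left out and never passed. The cone, horizontal cell and immediate early lists stayed lower, and called by camera at the preset correlation, under every scaling, filter and variance setting run for them and with each array left out. Their medians then ranged from -0.25 to -0.11, from -0.31 to -0.15 and from -0.96 to -0.55. With an estimated correlation the call was lost for the cone list (-0.20, adjusted p = 0.974), the horizontal cell list (-0.23, 0.123) and the immediate early list (-0.85, 0.306). It was also lost with an estimated correlation and each array left out: without knockout 1, 2 and 3 and wild-type 1, 2 and 3 the cone list stood at -0.21, -0.19, -0.17, -0.11, -0.17 and -0.25 (smallest adjusted p = 0.701), the horizontal cell list at -0.25, -0.22, -0.22, -0.25, -0.15 and -0.31 (0.196) and the immediate early list at -0.96, -0.77, -0.81, -0.91, -0.90 and -0.55 (0.272). With fry it was lost for the cone list (-0.20, 0.656) and the immediate early list (-0.85, 0.0679). The cause of these losses was not tested. Estimated correlations were 0.42 for the cone list and 0.41 for the immediate early list in place of 0.01. For the horizontal cell list the estimate of 0.02 lay close to 0.01, so a larger correlation is not shown to have removed its call. There camera with an estimated correlation gave p = 0.0041 before adjustment over the lists. Without Opn1sw and Pde6c the cone list stood at -0.18 (adjusted p = 0.0115; 0.974 with an estimated correlation). Over the list alone, horizontal cell members passing rose from 3 to 5 with the filter at the 50th percentile, with an intensity trend and with array weights. Deviations of samples with the same number correlated at 0.01, -0.09 and 0.08. This gives no sign of pairing by number, but with 3 arrays per group it cannot exclude a shared litter or culture run. With the number as a replicate block the counts stayed at 0 (smallest adjusted p = 0.740), Sall3 at -0.16, and the lists at -0.20, -0.23 and -0.85, all still called, while Arr3 at -0.51 lost its call over the cone list (adjusted p = 0.0608) and Fosb gained one over the immediate early list (adjusted p = 0.0408). At the preset correlation the rod photoreceptor list and the photoreceptor in general list were called without knockout 1 (0.03 and 0.03, adjusted p = 0.00816 for both) and with array weights (0.03 and 0.02), and the hypoxia and glycolysis list without knockout 3 (0.19) and without wild-type 3 (0.02). Without these arrays the calls were lost again (adjusted p = 0.648 and 0.673, and 0.994 and 0.950, with an estimated correlation), and with all arrays each of the 3 lists had an adjusted p = 0.974 with an estimated correlation. Of 152 named genes, 129 kept their direction in every setting and 23 did not. Among genes whose groups do not overlap, a state that chance gives to 10%, 297 were higher and 1962 lower after quantile normalization (86.9% lower), 803 and 654 as deposited (44.9%) and 426 and 936 after median centring (68.7%), so the balance of directions depends on the scaling. Other pseudocounts were not run because the values are already logarithms, and robust variances were not run for the lists. Signal over background is unknown, which limits fold changes of dim clusters.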

Other observations

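All tests of explanations in this part, including the splits of the arrays, were chosen after the results were seen. The test of a single array for the lists replaced an earlier one, by list medians and camera at the preset correlation, which had argued against a single array for all 3 lists. Outside the gene lists, and named here after their values were seen, Lhx1os, a transcript named for the strand opposite Lhx1, stood at -0.66 (SE 0.10) beside Lhx1 in the fit with 1 row per gene, and Tnr, which encodes the matrix glycoprotein tenascin-R, at -0.73 (SE 0.11). Neither passed in limma (adjusted p = 0.396 and 0.426). The ligand Angpt2 stood at -1.42 while the endothelial list had a median of 0.00 (-0.06 to 0.02 with an array left out). All 3 clusters of Gad2 were higher in knockout, at 0.34, 0.35 and 0.62, while Gad1 stood at -0.09.

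Among the 100 clusters with the smallest p, 82 were unnamed here and 18 were named. The unnamed clusters tc6955589 and tc6885024 stood at 2.14 and 1.40, and tc6972510 and tc6926553 at -1.08 and -0.98, without passing.

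The immediate early list was lower in knockout (-0.85). Scaling between the arrays is argued against, since the median closest to 0 under the other scalings was -0.81, and so is a single array as the whole cause, since the upper bound of the 95% interval of the list mean was at most -0.30 whichever array was left out. A difference between the groups in handling or harvest of the explants may account for the pattern and cannot be told apart from the genotype, because the labels give no harvest order and the hypoxia and glycolysis list, at 0.13, was not called and decides nothing. A response of the knockout tissue itself stays open and untested. For this list 1 of the 10 splits of the arrays, the real one, gave an absolute median as large, with 0.52 as the highest of the others, and 10 splits are too few for a share under 0.05.

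The cone pattern was led by Opn1sw, whose change minus that of Pde6c was -1.27 (95% interval -1.93 to -0.61). A single array is argued against as the whole cause for Opn1sw, which stood at -1.97 without wild-type 1. The mean of the cone list, -0.34, kept most of its size whichever array was left out (-0.41 to -0.28). For the list the test cannot decide, since the 95% interval included 0 without knockout 2, knockout 3, wild-type 1 or wild-type 2. It reached 0.0557 without knockout 3. Fewer cones with the same expression per cone would lower alike all genes expressed in cones alone. Whole retinas cannot show which list genes these are. Rows that go against an equal fall are Opn1sw minus Gnat2 at -2.17 (95% interval -2.92 to -1.42) and Pde6c minus Gnat2 at -0.90 (95% interval -1.15 to -0.65). Another is Cngb3 at 0.12 (95% interval -0.28 to 0.53) with a wild-type signal of 7.84. Fewer cones cannot be told apart from a change in expression per cone, which was not tested. The background of the clusters is unknown and may hide part of a loss, and so may expression in other retinal cells. For a fall as large as that of Opn1sw, Pde6c would need a background of 7.48 on the log2 scale, above 90.5% of the unnamed clusters. Gnat2, with a wild-type signal of 6.89 against 9.94 for Opn1sw and 9.01 for Pde6c, would need 6.67, above 83.6% of them. The 2 rows with Gnat2 therefore do not exclude an equal fall that background hides in Gnat2. For the 14 cone genes other than Opn1sw the needed background lay above 60.8% to 99.7% of them. For Cngb3, Thrb, Rxrg and Otop3 it exceeded the wild-type signal, at 7.99 against 7.84 for Cngb3. That only restates that their changes lay above 0, at 0.12, 0.01, 0.04 and 0.04. Each of their 95% intervals included 0, and each change turned sign in at least 1 alternative setting. The needed background therefore does not exclude a fall hidden by background in these genes. For the cone list 1 of the 10 splits, the real one, gave a median as large (0.20 in size, with 0.17 as the highest other), and 10 splits are too few for a share under 0.05.

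The horizontal cell list was lower in knockout (-0.23). The list mean, -0.29, kept most of its size whichever array was left out (-0.33 to -0.26). The test cannot decide on a single array as the whole cause, since the 95% interval included 0 without knockout 2, knockout 3, wild-type 1 or wild-type 2. It reached 0.0445 without knockout 2. Lhx1, Onecut1 and Tpm3 were called over the list alone whichever array was left out. A loss of inner retinal neurons in general that includes amacrine cells is argued against by the change of the horizontal list mean minus that of the amacrine list mean, -0.30 (95% interval -0.56 to -0.03). Against the ganglion cell list the difference was -0.22 (95% interval -0.49 to 0.04), so a loss shared with ganglion cells stays open, and so do fewer horizontal cells and lower expression per cell. For this list 1 of the 10 splits, the real one, gave a median as large (0.23 in size, with 0.14 as the highest other), and 10 splits are too few for a share under 0.05.

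The number of clusters at an unadjusted p under 0.05 was 4969, and 3 of the 10 splits gave as many, with 6051 as the highest of the others. That split set knockout 1 with wild-type 1 and wild-type 2. The count past the adjusted threshold was 0 in all 10 splits, and 10 splits are too few for a share under 0.05. Knockout 1 had the lowest mean correlation within its own genotype among the knockout arrays, 0.955, and an array weight of 0.39.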
